A study of Mus musculus with 6 samples.

How the data were processed

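RNA from C2C12 cells, a mouse myoblast line that can be made to fuse into myotubes, was sequenced in 6 libraries, 3 labelled wild-type and 3 labelled Gmppb-KO. Per the labels, cells were transfected with CRISPR/Cas9 plasmids carrying guides to exons 1 and 5 of Gmppb, kept in puromycin at 4 µg per ml, and expanded as monoclonal cells that were checked by sequencing of a PCR product; both genotypes were in culture for 2 days before lysis. The labels do not say whether the 3 knockout libraries come from 1 clone or several, or which culture medium was used. Groups and replicate numbers come from the sample titles. Nothing in the labels says that replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

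The authors deposited 1 table for the series. Its read counts per gene, per the file headers, are whole numbers with 1 column per library and were not normalized. The submitters' processing notes name FastQC, HISAT2, Subread, featureCounts, DESeq2 and the mouse build mm10; the annotation release and the strand setting of the counting are not given in the sources used here. The authors' FPKM columns equal the count per kilobase of the deposited gene length, scaled by a library size that is the DESeq2 size factor times the geometric mean of the count totals. The authors' log2 fold changes, p-values and adjusted p-values of knockout over wild-type are in the same deposited table. Refitting DESeq2 on the 19851 rows with a count sum above 1 gave log2 fold changes within 0.001 of theirs in 19851 rows, and 3850 adjusted p-values that DESeq2 leaves empty are written as 1 in the authors' table. The annotated gene length in bases, another value of the deposited table, was used only for length trends. The table holds 54532 rows with a gene name and 201 loci without one. These 201 loci took between 0.0699% and 0.195% of the counts of a library, and they were left out of library sizes and tests.

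Named genes were tested with edgeR 4.0.16 in R 4.3.3 (trimmed mean of M values normalization, filterByExpr, quasi-likelihood F test, 2-sided, design with the group as the only term). Benjamini-Hochberg adjusted p under 0.05 was the threshold, and calls with an absolute log2 fold change of at least 1 were also counted. Changes are relative to the trimmed mean scaling, under which the median log2 fold change of the 12786 tested genes was 0.11. Values per library are counts divided by the normalized library size in the usual unit of edgeR (CPM), means are given with the SD over n = 3, and the standard error (SE) of a log2 fold change was taken from the F statistic. A fold against libraries that all held 0 counts is a lower bound against 3 counts over the group. For groups with 1 to 3 counts the ratio of pooled counts is given with its exact 95% binomial interval, which covers counting error only. A set of 34 gene lists with 632 symbols was fixed before the data were examined, together with the tests, the alternatives and the rule for naming genes; 12 symbols were matched through older names. Lists with at least 3 tested members, 33 in all, were tested with camera of limma 3.58.1 at an inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over lists.

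The text names Gmppb, Gmppa, Dag1 and up to 4 tested members of the GDP-mannose and O-mannosylation lists; the 8 higher and 8 lower genes with the largest fold among those past the threshold, with a mean of at least 10 CPM in the higher group, no overlap between the 3 and 3 libraries and an ordinary gene symbol; and up to 4 members of each list with the smallest adjusted p among those past the gene test. Shares of counts were compared by an exact permutation test, 2-sided, whose smallest p with 3 against 3 libraries is 0.1. Principal components and Pearson correlations used log2 CPM with a prior count of 2 and are descriptive.

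Alternatives for the gene test were DESeq2 1.42.0, 3 other scalings, 2 other low-count filters, a replicate block, limma voom, leaving out each library, a test against a fold change of 1.5, limma on log2(FPKM + 1), and offsets that remove each library's trends with gene length and GC content. GC content was the mean over the annotated GENCODE transcripts of a gene, and 99.9% of tested genes had a value. Alternatives for the lists were the estimated inter-gene correlation, fry, another scaling, another filter, the block and leaving out each library; list tests and named genes with the trends removed, and shares without each library, were added after seeing the data.

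The same steps were tested on counts simulated for the knockout against wild-type comparison from the real means, library sizes and dispersions. Of 50 genes raised 4-fold and 50 raised 2-fold, 68% and 16% were recovered. Of 46 tested genes lowered 4-fold and 46 lowered 2-fold, 58.7% and 19.6% were recovered. Of 12372 unchanged genes, 7 were called. A change of 2-fold is therefore often missed in a design of this size. A length trend put into 1 simulated library gave a rank correlation of 0.32 between log2 fold change and gene length over 12571 genes, and 0.01 after the trends were removed. Library totals of 16011021 to 18566759 counts set the counting precision. The guide sequences in the labels were matched to the annotated mm10 transcript of Gmppb.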

Results

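The series compared C2C12 mouse myoblasts labelled wild-type with C2C12 cells labelled as knockouts of Gmppb, the subunit that joins mannose 1-phosphate and GTP into GDP-mannose, the sugar donor for N-glycans and for the O-mannosyl glycans of alpha-dystroglycan. The stated purpose was to learn how Gmppb affects muscle development. Messenger RNA was counted in 3 wild-type and 3 Gmppb-KO libraries. Total counts in named genes were 17700791, 17964344 and 16011021 in wild-type replicates 1, 2 and 3, and 18566759, 17927473 and 17616250 in Gmppb-KO replicates 1, 2 and 3. The first principal component held 61.1% of the variance and placed the wild-type libraries between -73.0 and -27.2 and the Gmppb-KO libraries between 23.4 and 90.1, with Gmppb-KO replicate 3 farthest out. Pearson correlations of log2 CPM were 0.955 to 0.983 among wild-type libraries, 0.924 to 0.979 among Gmppb-KO libraries and 0.839 to 0.941 between the groups.

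Gmppb messenger RNA was detected in every library of both genotypes, and its level did not pass the gene test. Gmppb (ENSMUSG00000070284, mm10 chromosome 9, 108049242 to 108052801) had 18.1, 20.9 and 23.9 CPM in wild-type replicates 1, 2 and 3 and 20.6, 16 and 13 CPM in Gmppb-KO replicates 1, 2 and 3. The means were 21 ± 2.94 and 16.5 ± 3.83 CPM (SD, n = 3 each), a log2 fold change of -0.34 ± 0.26 (SE) with an edgeR adjusted p of 0.459. The 95% interval of the log2 fold change, a normal approximation from the SE, ran from -0.85 to 0.17. With n = 3 per group it is likely too narrow. The exon 1 guide GAGCACTCCGAAGCCATTGG matched the plus strand at 108049573 to 108049592 and the exon 5 guide AGAGCCTTCCAAGTATGGTG at 108050465 to 108050484, each over 20 bases inside coding sequence and each followed by TGG. The expected cut sites are 892 bases apart and enclose 360 exon bases, 12.9% of the 2785 annotated exon bases, so the gene count mostly reads sequence outside that segment and is a weak check of the genotype labels. The 3' end of Gmppb overlaps Rnf123 on the minus strand by 1268 bases and Gm20529 on the plus strand by 1127 bases. Strand tells Gmppb reads from those of Rnf123 only if the counting used it, and does not tell them from those of Gm20529.

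**Figure D1:**
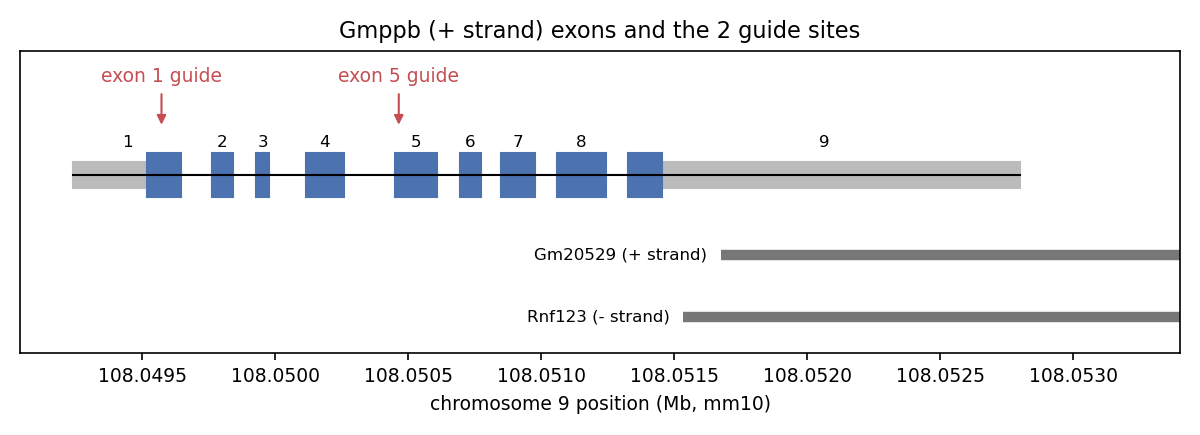
Map of Gmppb on mm10 chromosome 9 (position in Mb), with coding exon parts in blue, untranslated parts in grey, numbered exons, and the overlapping genes below. The guide sites, in exons 1 and 5, are 892 bases apart at their expected cuts, upstream of the overlaps with Rnf123 and Gm20529.

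None of the tested members of the GDP-mannose, O-mannosylation and N-glycosylation lists passed the edgeR gene test. Of 14 tested genes of GDP-mannose and dolichol-phosphate mannose synthesis, edgeR called 0, with 2 at an unadjusted p under 0.05; DESeq2 called 1 and limma voom 0. Gmppa, the regulatory partner of Gmppb, had 79.5 ± 17.5 CPM in wild-type and 99.0 ± 28.3 CPM in Gmppb-KO libraries (log2 fold change 0.32 ± 0.27, edgeR adjusted p = 0.506). Log2 fold changes were -1.35 ± 0.50 for Dpm3, 0.87 ± 0.35 for Nus1, -0.68 ± 0.30 for Dpm2 and -0.45 ± 0.28 for Mpdu1. Dag1, which encodes dystroglycan, had 132 ± 27.3 and 132 ± 37.5 CPM (log2 fold change -0.01 ± 0.26). Of 13 tested alpha-dystroglycan O-mannosylation genes, edgeR called 0 (2 at an unadjusted p under 0.05, 1 higher adjusted over the list alone, 1 by DESeq2, 0 by limma voom), with log2 fold changes of 0.85 ± 0.21 for Tmem5, also known as Rxylt1, and 0.81 ± 0.36 for B3galnt2. Of 27 N-glycosylation genes, 0 were called by edgeR, DESeq2 or limma voom, with 3 at an unadjusted p under 0.05. In the GDP-fucose list only Fuca2, a fucosidase gene, changed, rising 5.20-fold from 6.21 ± 0.968 to 32.4 ± 3.8 CPM, 1 of 13 members. Camera did not call the GDP-mannose, O-mannosylation, N-glycosylation and GDP-fucose lists (adjusted p = 0.494, 0.172, 0.276 and 0.412). Fry, which does not compare a list with other genes, called the last 3 higher (adjusted p = 0.0356, 0.0499 and 0.0163) and not the GDP-mannose list (adjusted p = 0.729); the ranges over the alternatives were 0.266 to 0.903, 0.0356 to 0.545, 0.0499 to 0.667 and 0.0163 to 0.691.

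Gmppb-KO libraries had lost most of the messenger RNA of Myod1, the transcription factor that defines myoblasts. Of 12786 genes tested, edgeR called 715, with 297 higher and 418 lower in Gmppb-KO libraries. A doubling or more was seen in 278 of the higher genes and a halving or more in 405 of the lower ones, 683 in all. In each of the 715 genes the 3 and 3 libraries did not overlap; over all tested genes this was so for 26.1%, where chance gives 10%. Myod1 (ENSMUSG00000009471, chromosome 7, 46376474 to 46379099) had 158 ± 5.76 CPM in wild-type and 0.453 ± 0.118 CPM in Gmppb-KO libraries, a 344-fold lower level (log2 fold change -8.43 ± 0.27, edgeR adjusted p = 9.82e-06). Wnt10a and Wnt7b, secreted Wnt ligands, had 31.3 ± 2.88 and 42.3 ± 3.22 CPM in wild-type libraries. Wnt10a had 1 count in the Gmppb-KO libraries together, a ratio of 1789 with a counting interval from 321 to 70705, and Wnt7b was 73.2-fold lower. Peg3, an imprinted zinc finger gene, had 21.8 ± 9.20 CPM in wild-type and 0 counts in each Gmppb-KO library, at least 426-fold lower. Ngfr, the low-affinity neurotrophin receptor, was 329-fold lower, Eva1b 339-fold, the peptide hormone gene Cck 91.4-fold and the monocarboxylate transporter gene Slc16a11 70.4-fold. Among called genes with a mean of at least 10 CPM in Gmppb-KO libraries, the largest rises were those of Scara5, a scavenger receptor that binds ferritin (248-fold, to 27.0 ± 4.77 CPM), the secreted carbonic anhydrase gene Car6 (101-fold, to 23.5 ± 1.99 CPM) and Oas1a, an interferon-induced sensor of double-stranded RNA (88.7-fold, to 33.9 ± 9.27 CPM). Prg4, which encodes lubricin, rose 75.1-fold, Myo18b 63.9-fold, Tmtc2 35.4-fold, the matrix gene Postn 29.7-fold and the G protein gene Gna14 23.8-fold. The folds of Tmtc2 and Postn rest on uneven Gmppb-KO values. In replicates 1, 2 and 3 these were 6.69, 8.06 and 22.5 CPM for Tmtc2 and 42.8, 68.6 and 196 CPM for Postn. Without wild-type replicate 1 the count of called genes was 331, without wild-type replicate 2 it was 444, and without Gmppb-KO replicate 2 it was 397, against 749 without Gmppb-KO replicate 3. DESeq2 called 1295 genes, and 713 of the 715 were among them.

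Many sarcomere and muscle calcium handling genes fell, by differing folds. Of 19 tested sarcomere and contractile genes, 13 were lower and 0 higher (14 lower adjusted over the list alone), among them Actn3 (19.6-fold, from 243 ± 30 to 12.4 ± 3.20 CPM), Mylpf (17.3-fold), Tnni2 (49.6-fold) and Tnni1 (15.1-fold). Of 19 tested genes of muscle calcium handling and metabolism, 10 were lower and 1 higher (15 lower and 1 higher adjusted over the list alone). The acetylcholine receptor gene Chrnd fell from 112 ± 3.54 to 10.0 ± 0.816 CPM and Chrng to 0.986 ± 0.441 CPM. The calcium channel gene Cacng1 was 2.81-fold lower, and Ckm, muscle creatine kinase, had 0 counts in Gmppb-KO libraries, at least 23.2-fold lower. The exception was Trdn, a sarcoplasmic reticulum protein gene named here after its value was seen, with 0, 1 and 2 counts in wild-type and 13, 59 and 123 in Gmppb-KO replicates 1, 2 and 3. Camera called the sarcomere list (adjusted p = 1.59e-13; 0.0419 with an estimated correlation) and the calcium list (adjusted p = 9.31e-10; 0.0642 with an estimated correlation, which ends the call). Members of the calcium list called lower numbered 3 without wild-type replicate 1 5 without Gmppb-KO replicate 2 and 7 without wild-type replicate 2 or Gmppb-KO replicate 1, and the Cacng1 call was lost without wild-type replicate 1.

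Among 18 tested myogenic regulators, 5 were lower and 0 higher (6 lower and 2 higher adjusted over the list alone). Besides Myod1 these included Myog, the regulator of terminal differentiation (11.3 ± 8.46 to 0.785 ± 0.0308 CPM), Pax7, the satellite cell factor (6.15 ± 0.853 to 0.576 ± 0.415 CPM), and Heyl, a Notch target (12.1-fold lower). Camera called this list at an adjusted p of 0.0307, and the call was lost with an estimated correlation (adjusted p = 0.408), with the range over the alternatives from 0.00731 to 0.408. Of 18 fusion genes, 2 were lower, namely the fusion proteins Mymk (20.2-fold, from 22.2 ± 1.48 CPM) and Mymx (40.9-fold, from 3.81 ± 0.974 CPM), and 4 were lower adjusted over the list alone; camera did not call the list (adjusted p = 0.179; range over the alternatives 0.0278 to 0.682), but did without wild-type replicate 2, without Gmppb-KO replicate 3 and with length and GC trends removed. Of 13 genes of the dystrophin-glycoprotein complex, 2 were lower, among them Sgca, alpha-sarcoglycan (6.29-fold, from 16.3 ± 4.93 CPM), and the list was not called (adjusted p = 0.795).

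**Figure D2:**
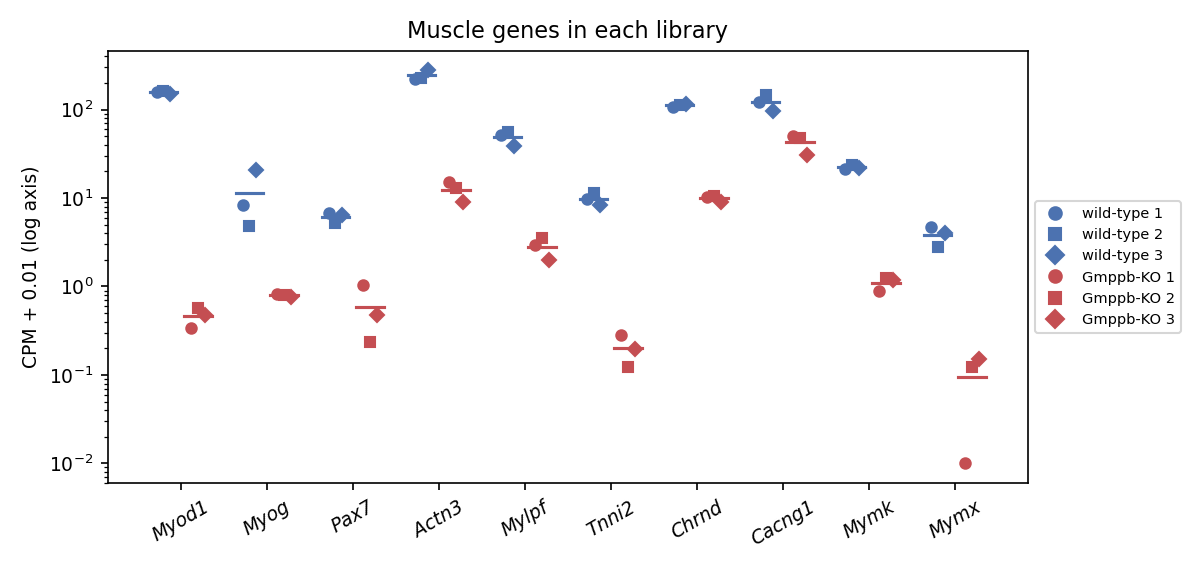
CPM + 0.01 on a log axis for 10 muscle genes, with 1 point per library (blue wild-type, red Gmppb-KO, shapes for replicates 1 to 3) and a bar at the mean of each group of 3. Myod1 stood at 158 CPM in wild-type and 0.453 CPM in Gmppb-KO libraries, and Chrnd at 112 and 10.0 CPM.

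Interferon response genes were higher in the Gmppb-KO libraries. Of 17 tested, 9 rose and 0 fell (12 rose adjusted over the list alone). Oas1a rose as given above, Irf9, a subunit of the interferon-activated transcription complex, rose 8.21-fold from 3.15 ± 0.268 to 25.9 ± 2.92 CPM, and Bst2, an antiviral membrane protein gene, rose 4.34-fold. Usp18, a negative regulator of interferon signalling, had 0 counts in wild-type libraries and 8.34 ± 1.64 CPM in Gmppb-KO libraries, at least 134-fold higher. Camera called the list (adjusted p = 1.43e-10; 0.0419 with an estimated correlation).

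Genes of the endoplasmic reticulum unfolded protein response were also higher, with 4 of 20 rising and 0 falling (10 rising adjusted over the list alone). These were the chaperone genes Hspa5 (2.61-fold, from 341 ± 68.2 to 889 ± 211 CPM), Dnajc3 (3.84-fold) and Pdia4 (2.69-fold), and Edem1, which acts in disposal of misfolded glycoproteins (2.01-fold). Camera called the list at an adjusted p of 2.38e-06 and not with an estimated correlation (adjusted p = 0.337; range over the alternatives 2.29e-07 to 0.337). With wild-type replicate 1 or 2 left out 0 of the 20 members were called, and without Gmppb-KO replicate 2 only 1 was. Of 18 Atf4 targets, Trib3, a pseudokinase induced by stress, was called, rising 2.81-fold from 36.2 ± 5.73 to 102 ± 22.5 CPM (4 rose adjusted over the list alone). The Atf4 list was called (adjusted p = 0.0162) but not with an estimated correlation (adjusted p = 0.545; range 1.54e-05 to 0.545), nor without wild-type replicate 3 or Gmppb-KO replicate 1; the Trib3 call was lost without wild-type replicate 1.

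Matrix genes moved in both directions. Of 20 tested collagen and matrix genes, 4 rose and 3 fell (10 and 3 adjusted over the list alone). Col1a1, a chain of type I collagen, rose 9.59-fold from 155 ± 30.2 to 1483 ± 313 CPM, while the type VI collagen genes Col6a2 and Col6a1 fell from 47.4 ± 2.15 to 4.31 ± 0.143 CPM and from 80.9 ± 10.8 to 15.6 ± 2.24 CPM. Bgn, a small proteoglycan gene, fell 5.36-fold. In the basement membrane list Col18a1 fell 21.5-fold from 194 ± 15.2 CPM and Lamb2, a laminin chain, rose 1.90-fold, 2 of 15 members; the Lamb2 call was lost under library-size scaling and without any of 4 libraries, wild-type replicates 1 and 2 and Gmppb-KO replicates 1 and 2. Ctgf, a secreted matricellular protein, rose 10.8-fold from 28.4 ± 6.24 to 306 ± 47.9 CPM and Ltbp2 fell 2.67-fold, 2 of the 20 TGF-beta and BMP response genes. The proteoglycan list had 2 of 20 members higher, Gpc4, with 1 count in wild-type libraries (ratio 91.6, counting interval 16.1 to 3653), and Hs6st2, a call lost without wild-type replicate 1, and the Wnt and Notch list had 2 of 17 lower, Notum and Heyl. The collagen, basement membrane, TGF-beta, proteoglycan and Wnt lists had camera adjusted p-values of 0.0630, 0.459, 0.459, 0.155 and 0.0630 and were not called. Over the alternatives these ran from 0.00944 to 0.725, 0.152 to 0.852, 0.0772 to 0.682, 0.0428 to 0.718 and 0.0240 to 0.573. The collagen list was called higher without wild-type replicate 3 or Gmppb-KO replicate 2, with a replicate block and with trends removed, the proteoglycan list higher without Gmppb-KO replicate 2 and with trends removed, and the Wnt list lower without wild-type replicate 2 or Gmppb-KO replicate 3.

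**Figure D3:**
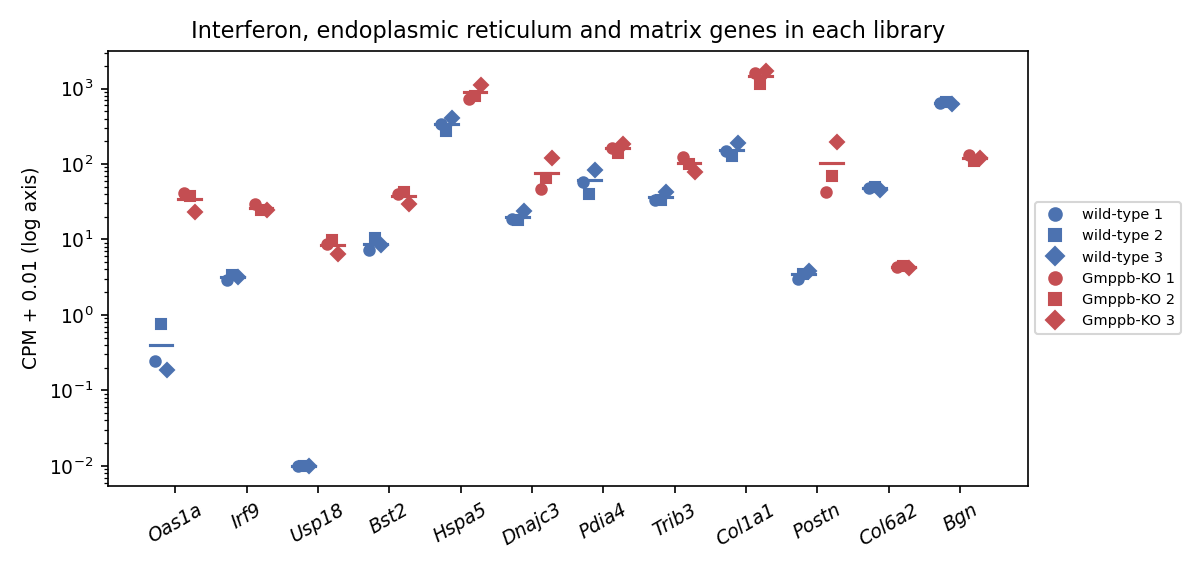
CPM + 0.01 on a log axis for 12 interferon, endoplasmic reticulum, Atf4 target and matrix genes, with 1 point per library (blue wild-type, red Gmppb-KO) and a bar at the mean of each group of 3. Usp18 had 0 counts in the wild-type libraries, Col1a1 rose from 155 to 1483 CPM and Col6a2 fell from 47.4 to 4.31 CPM.

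Proliferation genes did not pass the test. Of 27 cell cycle and replication genes, edgeR, DESeq2 and limma voom called 0, with 1 at an unadjusted p under 0.05. Among 18 p53 targets edgeR called only Cdkn1a, an inhibitor of cyclin-dependent kinases that also rises when myoblasts leave the cell cycle. Cdkn1a fell 2.47-fold from 449 ± 8.02 to 182 ± 35.4 CPM, a call lost without wild-type replicate 1. DESeq2 and limma voom each called 2 p53 targets, and 2 were higher and 2 lower adjusted over the list alone. In the autophagy and lysosome list 1 of 25, Map1lc3a, fell 2.57-fold, a call lost without any single library except Gmppb-KO replicate 3. By edgeR 0 members were called of 17 integrin and focal adhesion genes, 11 atrophy genes, 18 glycolysis genes, 21 nuclear oxidative phosphorylation genes, 12 mitochondrially encoded messenger RNAs and 8 histone genes. At an unadjusted p under 0.05 these lists had 3, 1, 2, 3, 3 and 1 members; DESeq2 called 2 integrin and 2 oxidative phosphorylation genes and 0 in the other 4 lists, and limma voom 0 in all 6.

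Camera called none of the lists of other cell types higher, while fry called the fibroblast and adipocyte lists higher. Of 10 tested fibroblast and fibro-adipogenic markers, 3 rose and 2 fell, with Mfap5 17.4-fold and Dcn 5.11-fold higher and Pdgfrb 2.99-fold and Osr1 8.35-fold lower. Of 5 adipocyte markers Lpl rose 8.35-fold to 35.1 ± 20.6 CPM. Fabp4, at 0 counts in wild-type libraries, was at least 15.3-fold higher but stayed low, at 0.958 ± 0.350 CPM in Gmppb-KO libraries. Of 3 tested epithelial markers Krt14 rose 4.23-fold and Cldn3 fell to 1 count over the group (counting interval of the ratio 11.2 to 2606). The Krt14 call was lost by limma voom and without any single library except Gmppb-KO replicate 3, that of Osr1 without any except Gmppb-KO replicate 1, those of Dcn and Fabp4 without wild-type replicate 1, and that of Fabp4 also without Gmppb-KO replicate 2. The fibroblast, adipocyte and epithelial lists had camera adjusted p-values of 0.459, 0.308 and 0.230, with ranges over the alternatives of 0.0432 to 0.842, 0.00408 to 0.867 and 0.0267 to 0.682. The lowest of the fibroblast and adipocyte values are those of fry, and the epithelial list was called lower without wild-type replicate 2 or Gmppb-KO replicate 2. Of 6 neural and Schwann cell markers, 3 fell, Ngfr, Nefl (4.35-fold) and Stmn2 (7.14-fold), and that list was called lower (adjusted p = 5.84e-07; 0.0576 with an estimated correlation, which ends the call). EdgeR called 0 of 4 osteoblast and chondrocyte markers, 0 of 3 endothelial and smooth muscle markers and 0 of 2 leukocyte markers, with 1, 1 and 0 at an unadjusted p under 0.05, 2, 1 and 0 called by DESeq2 and 0 by limma voom; the osteoblast and endothelial lists had camera adjusted p-values of 0.0630 and 0.343 (ranges 0.000743 to 0.667 and 0.144 to 0.667), and the leukocyte list had too few members for the list test. The osteoblast list was called lower without wild-type replicate 2, Gmppb-KO replicate 2 or Gmppb-KO replicate 3 and with trends removed. The mitochondrial, oxidative phosphorylation and histone lists had camera adjusted p-values of 0.0630, 0.0630 and 0.881, with ranges of 0.00177 to 0.682, 0.0165 to 0.682 and 0.579 to 1.00. The first 2 were called lower without Gmppb-KO replicate 2, with a replicate block and with trends removed, the mitochondrial list also without wild-type replicate 3 and the oxidative phosphorylation list also without Gmppb-KO replicate 1. In all, camera called 7 of 33 lists, 3 higher and 4 lower, and 2, the sarcomere and interferon lists, were called with an estimated correlation.

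**Figure D4:**
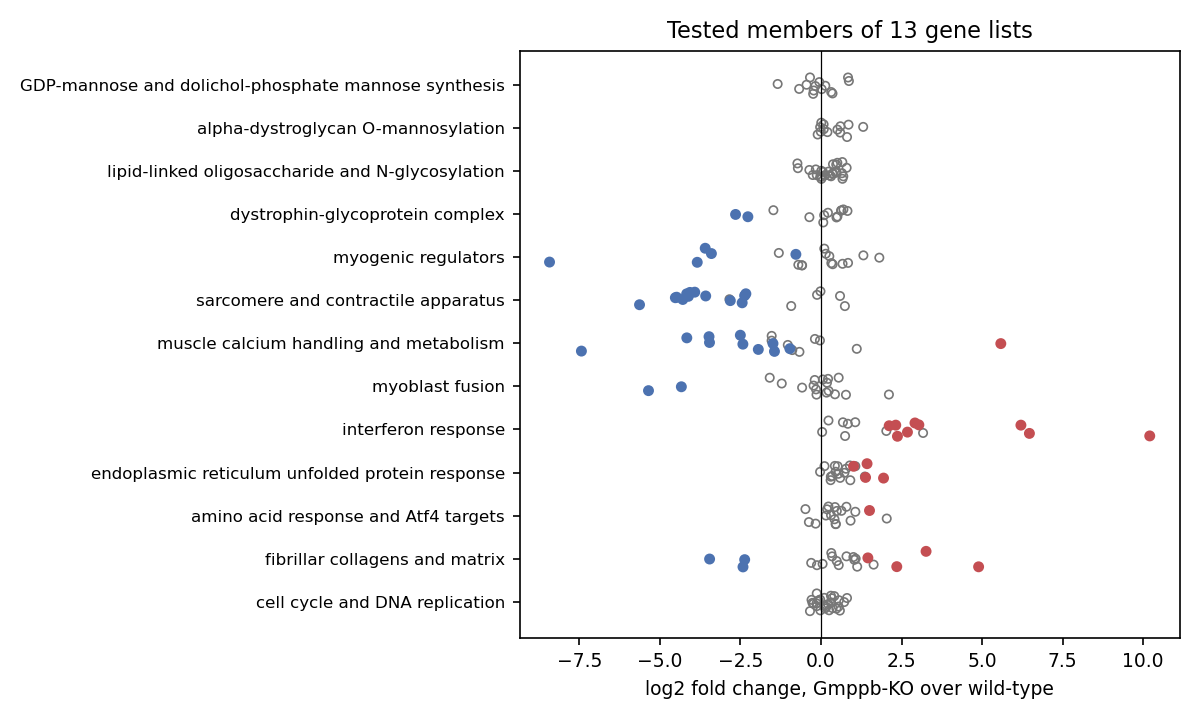
Log2 fold change (Gmppb-KO over wild-type) of each tested member of 13 gene lists, 1 point per gene, filled where edgeR called it (red higher, blue lower) and open where it did not. Filled points lie to the left in the sarcomere list (13 of 19) and to the right in the interferon list (9 of 17), with none in the GDP-mannose list.

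Libraries also differed in the lengths of the genes that took their counts. Genes over 5000 bases took 21.5%, 18.7% and 26.2% of counts in wild-type replicates 1, 2 and 3 and 24.2%, 23.2% and 33.7% in Gmppb-KO replicates 1, 2 and 3, with group means of 22.1% ± 3.78 and 27.0% ± 5.79 (exact permutation p = 0.4). Ribosomal protein genes, which are short, took 11.8% ± 2.80 and 9.28% ± 2.47 (exact permutation p = 0.4), the 100 most abundant genes 29.4% ± 3.81 and 24.5% ± 3.65 (exact permutation p = 0.3) and mitochondrial messenger RNAs 1.64% ± 0.190 and 1.49% ± 0.241 (exact permutation p = 0.6); 0.1 is the smallest p that 3 against 3 libraries can give. The median log2 fold change was -0.34 over 1637 tested genes of up to 1500 bases and 0.30 over 5040 genes of more than 5000 bases. Without Gmppb-KO replicate 3 these medians were -0.20 and 0.01. The 23 muscle genes and 9 interferon genes called above were all called without that library as well.

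**Figure D5:**
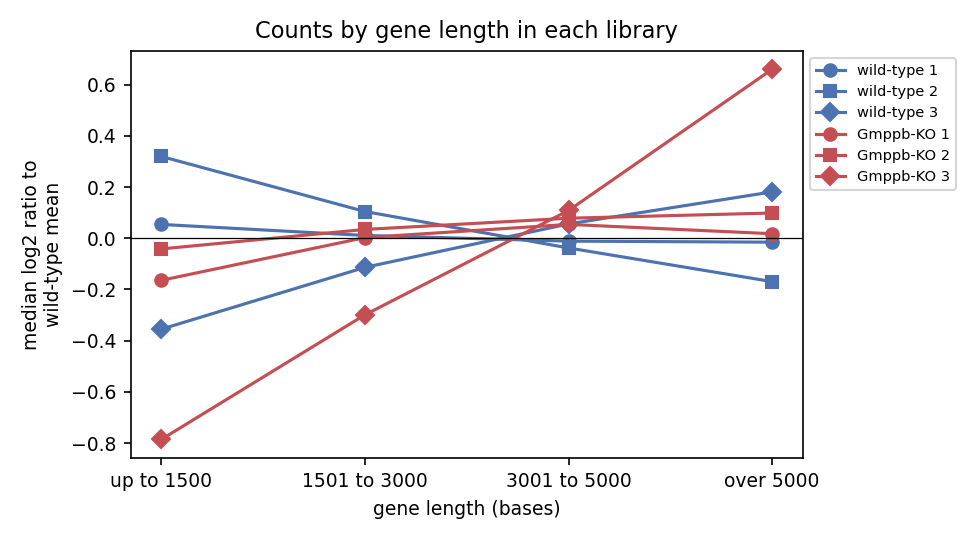
Median log2 ratio of each library to the wild-type mean, over the tested genes of 4 length classes (gene length in bases), 1 line per library (blue wild-type, red Gmppb-KO). Gmppb-KO replicate 3 runs from -0.79 in genes of up to 1500 bases to 0.66 in genes over 5000 bases.

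The authors' deposited table held 1295 named genes at an adjusted p under 0.05, with 529 higher and 766 lower in Gmppb-KO cells. Of the 715 genes called by edgeR, 713 were among them, each in the same direction, and 2 were not. In the authors' deposited table Gmppb had a log2 fold change of -0.40 (adjusted p = 0.478), Gmppa 0.25 (adjusted p = 0.712), Dag1 -0.07 (adjusted p = 0.920) and Myod1 -8.52 (adjusted p = 6.16e-106).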

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

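The tests of dilution, of another cell line, of single-library slopes and of the transfection history were chosen only after the result was seen, and the Y-linked genes were narrowed to 4 after another Y-assigned gene, Gm47283, was seen to have counts.

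The table holds 201 loci without a gene name, which the comparisons above leave out, and some of them differed between the groups. When they were tested with the named genes by edgeR, 97 passed the filter and 16 were called, 11 higher and 5 lower in Gmppb-KO libraries. A locus on chromosome X at 9672743 to 9681428, 9740 bases from Dynlt3, had 0, 0 and 1 counts in wild-type replicates 1, 2 and 3 and 250, 284 and 394 counts in Gmppb-KO replicates 1, 2 and 3. A locus on chromosome 14 at 19225970 to 19229396 had 0 counts in the wild-type libraries and 133, 183 and 218 in the Gmppb-KO libraries, at least 151-fold higher.

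Muscle genes were lower in Gmppb-KO libraries, with 23 members of the sarcomere and calcium lists called. Removing each library's trends with gene length and GC content left 100% of the 23 called lower. Their median log2 fold change went from -3.48 to -3.31, which argues against those trends as the whole cause. Of all 715 called genes 693 stayed called as well, so keeping the call does not set the muscle genes apart. Dilution by cells without these transcripts predicts 1 common fold, but 57.1% of the 21 members with over 3 counts in Gmppb-KO libraries had an interval that left out the common log2 fold change of -2.83, from -0.97 for Chrna1 to -5.63 for Tnni2. These intervals rest on a normal approximation and are likely too narrow, so the share may be too high. Another cell line of the same sex under the knockout label cannot be told apart from a clone, since the Y-linked genes Kdm5d, Uty, Ddx3y and Eif2s3y had 0 counts in all 6 libraries. An effect of losing Gmppb remains open as well, because the labelled genotype differs between the groups together with transfection, selection and cloning.

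Interferon response genes rose, with 9 of 17 called. With the length and GC trends removed, 100% of the 9 stayed called higher, near the rate over all calls (693 of 715). Their median log2 fold change went from 2.92 to 2.97, which argues against those trends as the cause for these 9 genes. The rise may come from transfection, puromycin selection or single-cell cloning rather than loss of Gmppb. Transfection, selection and cloning cannot be told apart from the knockout here, because 0 libraries came from cells that went through those steps without a Gmppb guide.

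Long genes were higher and short genes lower in the Gmppb-KO libraries on average. The slopes of log2 CPM on the doubling of gene length overlapped between the groups (-0.21 to 0.06 in wild-type, -0.06 to 0.34 in Gmppb-KO libraries), and 14.7% of the difference of the group means was left without Gmppb-KO replicate 3. The pattern may therefore belong to single libraries. More nuclear RNA or genomic DNA in Gmppb-KO replicate 3 is a candidate explanation: with the trends removed, its ratio to the other Gmppb-KO libraries was 0.22 higher on the log2 scale for 431 long non-coding genes than for 11567 protein-coding genes (bootstrap interval over genes 0.16 to 0.28), while the largest such value in another library was 0.09 and the lowest -0.21. The nuclear RNAs Malat1, Neat1 and Xist, looked at after their counts were seen, were 11-fold, 6-fold and 8.11-fold higher in Gmppb-KO replicate 3 than in the mean of replicates 1 and 2.

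With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split called 715 genes and the highest of the other splits 0, and it was 1 of the 10 with a count as large. Every other split mixes wild-type and Gmppb-KO libraries, so a difference between the genotypes widens the spread within its groups. Its count of 0 therefore does not show what chance alone would give. The real split called 7 lists and the highest of the other splits 12, with 5 of the 10 splits calling at least 7. List calls at a preset correlation therefore also follow structure among the libraries, such as the split that set Gmppb-KO replicates 1 and 3 with wild-type replicate 1. With an estimated correlation the real split called 2 lists and every other split 0, a contrast with the same limit.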

How the results depend on the processing

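The list tests and named genes with trends removed, and the shares without each library, were chosen after seeing the data; the other alternatives were planned. Total, higher, lower and at least doubled or halved calls, 715, 297, 418 and 683 in the reported fit, were 1295, 528, 767 and 1147 by DESeq2 and 1419, 639, 780 and 1320 without the low-count filter, which tested more genes. The test against a 1.5-fold change called 473 genes, 187 higher. Removing length and GC trends gave 1214, 558 and 656 calls in total, higher and lower, and limma on log2(FPKM + 1), which shrinks the change of low genes, gave 397 with a doubling or halving; the cause of the larger count was not tested. Leaving out 1 library gave 331 to 749 calls (119 to 353 higher, 212 to 458 lower, 331 to 716 with a doubling or halving); the lowest came without wild-type replicate 1 (331), Gmppb-KO replicate 2 (397) and wild-type replicate 2 (444), in fits with fewer samples. No gene shared with the reported calls changed direction under any alternative. Library-size scaling called 567 genes and shifted the median log2 fold change of all genes by 0.16, the other scalings by less than 0.1. Called lists, 7 as reported, were 2 with an estimated correlation, 12 by fry, which does not compare a list with other genes, 12 with trends removed and 6 to 13 without 1 library (11 without wild-type replicate 2, 13 without Gmppb-KO replicate 2); the cause was not tested. Adjusted p over the list alternatives ran from 4.01e-17 to 0.0419 for the sarcomere, 9.00e-13 to 0.0419 for the interferon, 2.37e-11 to 0.0642 for the calcium and 1.16e-08 to 0.0576 for the neural list. The Gmppb log2 fold change kept its sign (-0.61 to -0.10) and its side of the threshold under all 16 alternatives. For the other named genes 1127 of 1182 fits kept the call and direction, 49 lost the call, 6 gained it and 0 reversed.

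Whether replicate numbers shared between the groups pair the libraries was not settled. Deviations from the group means correlated at -0.18, 0.51 and 0.42 for replicates 1, 2 and 3. Wild-type replicates 2 and 3 correlated best with the Gmppb-KO library of the same number, but wild-type replicate 1 correlated best with Gmppb-KO replicate 2. With a replicate block the calls were 1618 in total, 673 higher, 945 lower and 1058 with a doubling or halving, and 9 lists were called. In counts simulated with these library sizes, dispersions and 3 libraries per group, 16% of genes raised 2-fold were recovered.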

Other observations

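The tests of paternal genes on other chromosomes, of whole chromosomes and of the Gmppb segment were chosen after the result was seen; the Snrpn test was set down before its counts were seen, and the Mkrn3 count test was added after.

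Imprinted genes of chromosome 7 split by parental allele, a grouping made after Peg3 and Ndn had been seen at 0. The paternally expressed genes Peg3, Usp29, Snrpn, Ndn and Peg12 had 0 counts in each of the 3 Gmppb-KO libraries. In wild-type libraries they had means of 21.8, 2.02, 6.68, 6.60 and 1.29 CPM, which makes them at least 426-fold, 39.3-fold, 127-fold, 126-fold and 24.4-fold lower. Peg3 and Usp29 lie at 6.7 to 7.0 Mb and the other 3 near 60 to 62.5 Mb. The maternally expressed genes H19, Zim1, Cdkn1c and Ube3a, the last imprinted only in neurons, were all detected in the Gmppb-KO libraries, with log2 fold changes of 0.33, 1.77, -1.17 and 1.29 that did not pass the edgeR test. Mkrn3, paternally expressed in the same cluster, had 12 counts over the wild-type and 8 over the Gmppb-KO libraries, where 10% of the wild-type level would give 1.41 (binomial p = 0.000596, counting error only).

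A candidate explanation is loss or silencing of the paternal copies of imprinted genes on chromosome 7 in the knockout line. Snrpn was named first before its counts were seen, and its level was 0% of wild-type in the Gmppb-KO libraries, but the same prediction of under 10% was not met by Mkrn3, which lies between Ndn and Peg12 and has few counts, so the explanation stays open. A general loss of paternally expressed genes is argued against, since 0 of 7 tested genes of other chromosomes were under 10% of the wild-type level, 5 were over 50% and Mest was at 18.5%; the criterion was reworded, and Copg2 and Gnas taken off as not reliably paternal, after their values were seen. The median log2 fold change of the 932 tested chromosome 7 genes was 0.01 with trends removed, which speaks only to the chromosome as a whole. Focal loss and silencing were not tested, nor was a link to Myod1 on the same chromosome at 46.4 Mb.

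Chromosomes differed in their median change, which may reflect gains or losses of chromosomes in the knockout line. With trends removed, 13 of 20 chromosomes had a median log2 fold change beyond that of random genes (permutation, adjusted p under 0.05) with the same sign in each Gmppb-KO library. The permutation treats genes as independent, so small medians weigh little. For chromosome 17 the medians were -0.30, -0.28 and -0.22 in Gmppb-KO replicates 1, 2 and 3, and each of its 5 windows of 20 Mb was below 0. For chromosome 16 they were 0.20, 0.21 and 0.25, with each of 4 windows above 0. Windows also had 1 sign on chromosome 14 (4 of 4 above 0, median 0.19) and chromosome 15 (6 of 6 below 0, median -0.17). The same held for chromosome 2 (below 0, median -0.085) and for chromosomes 6 and 9 (above 0, medians 0.077 and 0.077). Windows of 1 sign therefore do not mark out chromosomes 14 to 17. Only chromosomes 16 and 17 lay, in each Gmppb-KO library, beyond the largest median that any library showed against the others of its own group, 0.18. That largest value came from chromosome 18. Measured against within-group medians of the same chromosome, the group median of all 13 chromosomes lay beyond them. On chromosome 14 it was 0.19 against at most 0.027 in size, and on chromosome 15 -0.17 against at most 0.033. The permutation adjusted p of chromosomes 14 to 17 was 0.000333, from the smallest p that 10000 permutations can give. Chromosomes 1 and 2 had the same value.

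If the segment between the guide sites were lost on all alleles with no other effect, the Gmppb log2 fold change would be -0.20 with all exon bases counted, and -0.31 if reads in exons of Rnf123 and Gm20529 were not assigned. The measured interval of -0.85 to 0.17 holds both values and 0, so the counts cannot tell whether the segment is missing.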
